A study of Mus musculus with 12 samples.

How the data were processed

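RNA-seq was made from NR5A1(+) cells of fetal mouse gonads, with 12 libraries in 5 groups. Per the labels' protocols, gonads of E10.8 embryos were taken with the aorta, mesonephros and mesenchyme, and were cultured on filters for 19.2 h in DMEM with 10% horse serum. Dfo, the iron chelator deferoxamine, was given at 150 µM. Per the labels' protocols, total RNA was taken from NR5A1(+) cells and libraries were made with the SMART-Seq Stranded Kit. The genotype in the labels, Nr5a1-hCD271, places a cell-surface tag under the Nr5a1 gene. The same protocol text stands on the E11.5 samples, so how those were collected is not settled by it. The groups were control XY in culture (n = 3), Dfo XY in culture (n = 3), control XX in culture (n = 2), E11.5 XY (n = 2) and E11.5 XX (n = 2). Nothing in the labels says that replicates come from separate embryos or litters, so p-values measure the spread between these samples.

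The deposited values are TPM, transcript abundances scaled to the same total in each library, 1 file per library, with 24411 gene symbols each and the same symbols in all 12 files. Per the submitters' processing notes, STAR 2.7.10b, RSEM, R 4.1.2 and the mm10 genome were used, and the version of RSEM, the annotation and any filter are not given in the sources used here. TPM keeps no record of sequencing depth. The depth of each library is therefore unknown, and no counting interval or detection limit was computed. Of the symbols, 23376 were found in GENCODE M21, which gave the positions on mm10. Fold changes were computed on log2(TPM + 1), which understates the change of genes with low values, and a gene listed at 0 in a whole group was given no fold.

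Differences between groups were tested with limma 3.58.1 in R 4.3.3, on log2(TPM + 1), with 1 coefficient per group, a trend of the variance on the mean level and all 12 libraries in 1 fit. Genes with TPM of at least 1 in at least 2 libraries were kept, which left 16133. P-values were adjusted by Benjamini-Hochberg within each contrast, and a gene was called at an adjusted p below 0.05. Every adjusted p given for a gene comes from limma with this adjustment. The contrasts were Dfo XY against control XY, control XY against control XX and Dfo XY against control XX in culture, E11.5 XY against E11.5 XX, control culture against E11.5 in each sex, and the sex difference in culture minus that at E11.5, which is the interaction. The tests, the alternatives, the gene lists and the rule for naming genes were chosen before the data were examined, except where stated.

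Gene lists for gonad development, iron and oxygen biology, cell cycle, stress and other cell types of the sample were written from textbook knowledge. Of 29 lists, 28 were tested, and the list of mitochondrially encoded respiratory subunits was not analysed here. Some genes stand in more than 1 list, such as Kdm3a, Atf3 and Sesn2. Each list was compared with all other genes by camera, the competitive set test of limma, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 28 lists. A second value for each list used a correlation estimated from the residuals. The number of called members is given over all genes tested and also adjusted over the list alone. The distance of a list is its median log2 change minus the median of all genes. Genes named were, in each comparison of groups, those with the largest called changes (8 in each direction for Dfo XY against control XY, 6 elsewhere) with a mean of at least 5 TPM in either group and no overlap between libraries, leaving out predicted-gene symbols, Y-linked genes and Xist. To these were added up to 4 called members of each list described, by smallest adjusted p, and Sry, Sox9, Fgf9, Amh, Wnt4, Foxl2, Fst, Nr5a1, Tfrc and Kdm3a.

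The method was tested on simulated data built with the group sizes of the study before it was used. In a simulated Dfo comparison of 15707 genes, 41.8% of genes changed 1.5-fold were recovered. Of those changed 2-fold 79.1% and of those changed 4-fold 97.0% were recovered, and 8.81% of the calls were false. In a simulated E11.5 comparison of 15160 genes, 16.4% of genes changed 1.5-fold were recovered. Of those changed 2-fold 53.7% and of those changed 4-fold 92.4% were recovered, and 4.42% of the calls were false. The changed genes were drawn from those with a mean of at least 5 TPM. The simulated noise held no correlation between genes or between libraries, so these rates need not be those of the real data.

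The replicate numbers of control XY and Dfo XY were checked for pairing by correlating, across genes, the deviations of the libraries from their group means. Libraries of the same number had r of 0.21, 0.12 and 0.34, each above the 0.1 taken as pairing, but control replicate 1 also had r of 0.14 with Dfo replicate 2, and control replicate 2 had 0.18 with Dfo replicate 1. The values set replicate 3 apart from replicates 1 and 2 and did not match replicates 1 and 2 by number. Genes are not independent replicates, and no p was computed from them. The other groups of equal number gave r between -0.02 and 0.05. A fit with the replicate number as a further term was among the alternatives.

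The alternatives were pseudocounts of 0.1 and 5, no filter and a filter at 5 TPM, median-of-ratios scaling, quantile normalization, removal of the 50 genes with the highest mean TPM, the replicate block, moderation with no trend or robust, array weights, only the libraries compared, leaving out each library, and for lists the estimated correlation and the self-contained test fry. For genes biased by sex at E11.5, the 200 genes with the largest difference, and a list that kept Y-linked genes and Xist, were also used. Alternatives chosen after the data were seen were removal of 1328 short non-coding RNA genes, averaging of replicates 1 and 2 in each cultured XY group, and leaving out both Dfo libraries that held Xist. No library was left out of the reported fit, and some genes that the rule names are not reported here. Genes with near-identical copies share reads, and Rps27, Amd1, Rpl10l, Snora23, H2-L, Ifna1 and the globin genes are uncertain for that reason.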

Results

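The 12 libraries measured gene expression as TPM in NR5A1(+) cells of XY and XX fetal mouse gonads, the somatic cells that carry the nuclear receptor NR5A1. Cultured gonads gave 3 control XY, 3 Dfo XY and 2 control XX libraries, and gonads at E11.5 gave 2 XY and 2 XX libraries. Between 14578 and 15456 symbols had a value above 0 in the XX libraries, and between 16147 and 18931 in the XY libraries. At TPM of at least 1 the ranges overlapped, with 13161 to 13363 in XX and 13133 to 16001 in XY. Whether genes listed at 0 in XX reflect this lower number of symbols was not tested. The depth of the libraries is unknown because TPM does not keep it. In the tests, 16133 genes were compared. Values are means ± SD over the libraries of a group, and log2 changes are given ± SE from limma.

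Y-linked genes followed the sex in the labels. Sry (chromosome Y, 2662471 to 2663658, mm10), the gene that starts testis development, was listed at 0 in all 4 XX libraries and stood between 2.40 and 53.4 TPM in the XY libraries. Xist (chromosome X, 103460366 to 103483254), the RNA of X inactivation in XX cells, had 170.3 ± 6.36 TPM (SD, n = 2) in cultured XX and 136.7 ± 17.5 TPM (SD, n = 2) in E11.5 XX. It had at most 0.90 TPM in 6 of the XY libraries. The exceptions were Dfo XY replicate 1, with 13.6 TPM of Xist, and Dfo XY replicate 2, with 24.6 TPM. Their Y-linked genes stood at 75.9 and 70.2 TPM in sum, beside 94.5 TPM in Dfo XY replicate 3. Control XY replicates 1 and 2 also lay below replicate 3, with sums of 80.8, 82.0 and 112.75 TPM.

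Replicates 1 and 2 of the cultured XY groups lay close to each other. Over 3051 well-expressed genes the median absolute log2 difference was 0.06 between control XY replicates 1 and 2 and 0.07 between Dfo XY replicates 1 and 2. Between replicate 3 and each of these it was between 0.19 and 0.20. Over all 24411 symbols, 330 values above 0 were identical to the 2 decimals listed in control XY replicates 1 and 2. In Dfo XY replicates 1 and 2 there were 111 such values. In the other pairs compared, each within a group, between 27 and 40 values were identical. Whether these libraries come from separate gonads is not given in the sources used here.

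The RNA component of RNase P, Rpph1 (chromosome 14, 50807449 to 50807767), took a share of TPM that differed between groups. It made up 19.3%, 20.3% and 15.3% in control XY and 23.6%, 23.2% and 19.5% in Dfo XY. Cultured XX had 7.20% and 6.96%, E11.5 XY 12.2% and 12.02%, and E11.5 XX 8.57% and 11.47%. Because TPM is a share, a larger share of 1 RNA lowers all others, and the direction of many small changes moved with the scaling.

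The main comparison asked which genes of XY gonadal cells changed when iron was chelated in culture. Dfo raised genes of the response to low oxygen and of glucose use, genes of several stress responses and the transferrin receptor gene Tfrc, and it lowered Sry. Sry fell by 2.50 ± 0.33 on the log2 scale, from 27.1 ± 16.0 TPM (SD, n = 3) to 3.60 ± 1.04 TPM (SD, n = 3). The 3 control libraries had 19.5, 16.4 and 45.6 TPM of Sry and the 3 Dfo libraries 4.23, 2.40 and 4.18 TPM (limma, adjusted p = 0.000359). The glucose transporter gene Slc2a1 (chromosome 4, 119108711 to 119137983) rose from 41.7 ± 6.19 to 544.1 ± 134.2 TPM (SD, n = 3 in each group).

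Of the 39 hypoxia-response genes measured, 33 rose and 0 fell, and 33 rose and 0 fell when adjusted over the list alone. P4ha2, a collagen prolyl hydroxylase, rose by 4.09 ± 0.20, and Ero1l, an oxidase of the endoplasmic reticulum, rose 17.1-fold. Vegfa, the vascular growth factor, went from 122.1 ± 15.9 to 676.2 ± 51.0 TPM (SD, n = 3). Of 17 glycolysis enzymes, 14 rose and 1 fell, with the same counts adjusted over the list alone (14 and 1). Pgk1 rose by 2.79 ± 0.15 and Gpi1 by 2.40 ± 0.10. The distances of these lists from the median of all genes were 2.37 (camera, adjusted p = 1.04e-54) and 2.12 (adjusted p = 2.90e-27). With an estimated correlation their adjusted p were 0.00647 and 0.0219.

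Among 23 genes of iron handling, 2 rose and 2 fell, and the counts adjusted over the list alone were also 2 and 2. Tfrc (chromosome 16, 32608920 to 32632794), the receptor that takes up transferrin iron, went from 67.2 ± 14.99 to 249.2 ± 23.9 TPM (SD, n = 3), a log2 change of 1.89 ± 0.14 (limma, adjusted p = 3.10e-06). Hmox1, which breaks down haem, rose by 1.94 ± 0.20. The iron transporter gene Slc11a2 fell by 0.57 ± 0.14 and the iron chaperone gene Pcbp1 by 0.35 ± 0.09. The Slc11a2 call ended without control XY replicate 2, Dfo XY replicate 1 or Dfo XY replicate 2 (limma, adjusted p = 0.0507, 0.0676 and 0.0587), and the Pcbp1 call without control XY replicate 1 (0.0666). The list as a whole did not differ from other genes (camera, adjusted p = 0.596), and its median and mean lay below 0 while the test pointed up.

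Stress-response genes rose together. Of 30 genes of the integrated stress response, 23 rose and 0 fell (25 and 1 adjusted over the list alone), among them Trib3 by 3.36 ± 0.26, Atf3 by 3.04 ± 0.20 and Atf4, the transcription factor of this response, by 1.48 ± 0.10. Of 23 immediate early genes 16 rose and 0 fell (18 and 0 adjusted over the list alone), with Junb up by 1.85 ± 0.18 and Jun by 1.33 ± 0.13. Of 24 cholesterol synthesis genes 17 rose and 0 fell (20 and 0 adjusted over the list alone), with Cyp51 up by 1.24 ± 0.08. The distances from all genes were 1.45, 1.15 and 0.93 (camera, adjusted p = 3.19e-30, 1.12e-21 and 2.81e-24), and with an estimated correlation the adjusted p were 0.00177, 0.0236 and 0.0295.

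Of 30 p53 targets 15 rose and 0 fell (15 and 2 adjusted over the list alone), such as Sesn2 by 1.77 ± 0.15 and Btg2 by 1.67 ± 0.17 (camera, adjusted p = 1.56e-11; adjusted p = 0.110 with an estimated correlation). Sesn2 also stands in the list of the integrated stress response. Of 22 genes of the unfolded protein response 9 rose and 1 fell (10 and 1 adjusted over the list alone), with Herpud1 up by 1.80 ± 0.17 and the chaperone gene Hspa5 by 0.62 ± 0.10 (camera, adjusted p = 3.49e-08; adjusted p = 0.0821 with an estimated correlation). Of 21 YAP and serum response targets 5 rose and 2 fell, also adjusted over the list alone (5 and 2). Ctgf rose by 1.70 ± 0.26, and Myl9 fell by 1.36 ± 0.11. This last list had a camera adjusted p of 0.00533, and adjusted p = 0.402 with an estimated correlation and 0.165 without Dfo XY replicate 3.

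**Figure D1:**
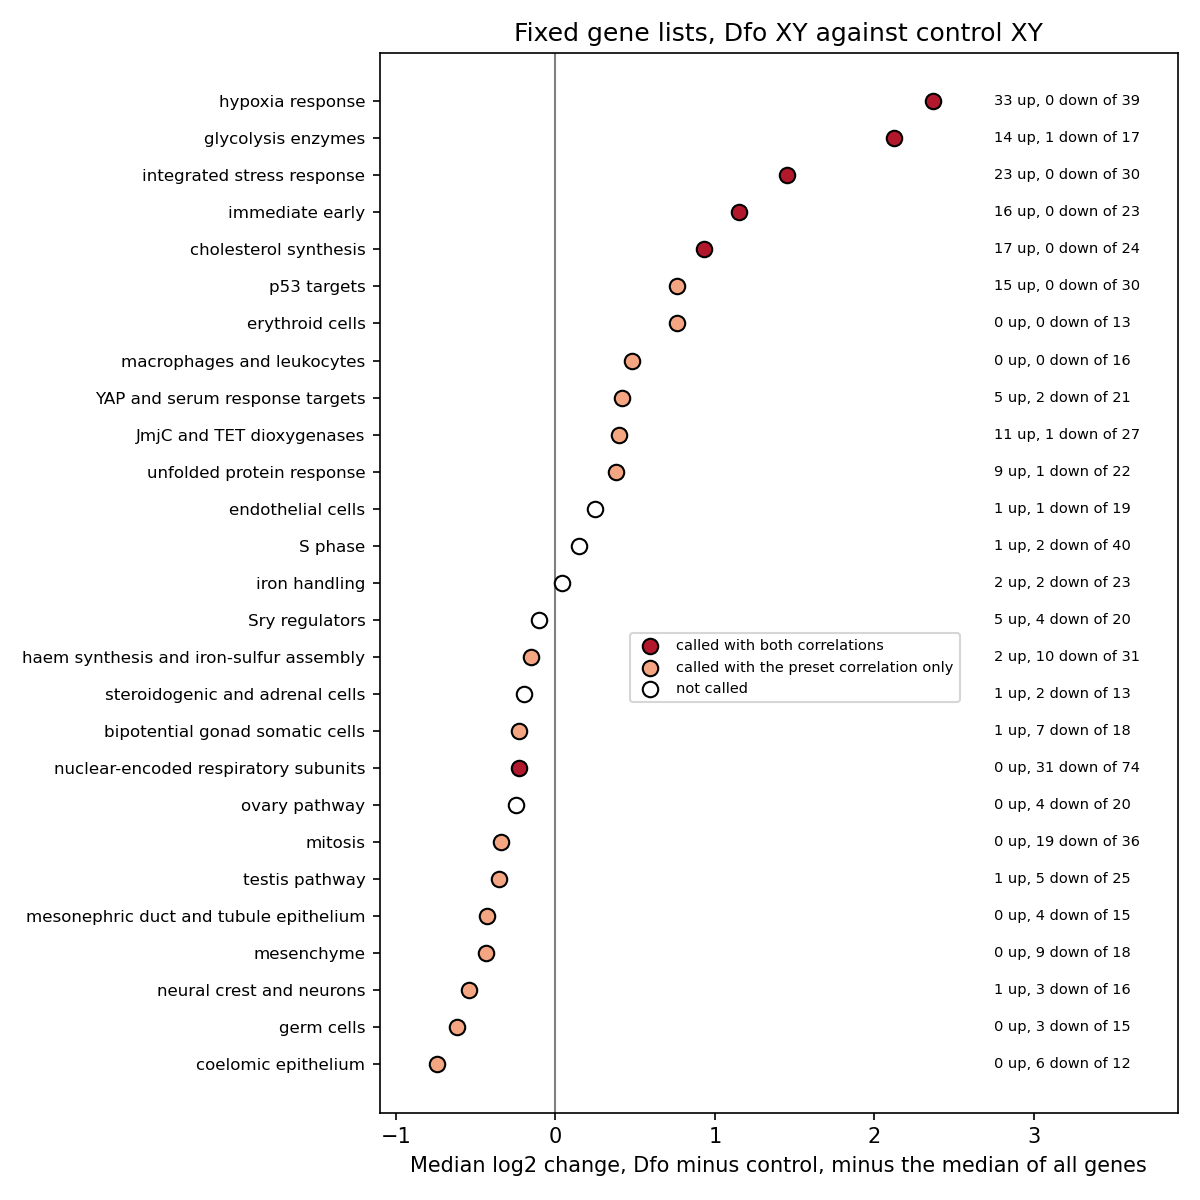
Change of the fixed gene lists in Dfo XY against control XY in culture (3 libraries each), as the median log2 change of each list minus the median of all genes. Filled dark points were called with the preset and the estimated correlation, light points with the preset correlation only and open points not at all. Y-linked genes and Xist are not drawn, and the hypoxia response and glycolysis lists lay farthest above all genes, at 2.37 and 2.12.

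Among genes of gonad development, Sry was the member of the testis list with the smallest adjusted p. Of 25 testis pathway genes 5 fell and 1 rose (6 and 1 adjusted over the list alone). Dmrt1 fell by 1.12 ± 0.23 and Gadd45g, an activator of the pathway upstream of Sry, by 0.61 ± 0.13, and Mybl1, a factor of meiotic germ cells, rose by 1.09 ± 0.30. The Mybl1 call ended when any of 5 libraries was left out (limma, highest adjusted p = 0.103, without Dfo XY replicate 3), and the calls for Dmrt1 and Gadd45g ended without both Dfo libraries that held Xist (-0.86 and -0.56; limma, adjusted p = 0.134 and 0.0919). The list lay -0.35 from all genes (camera, adjusted p = 0.00424), with adjusted p = 0.112 with an estimated correlation and 0.0615 without Dfo XY replicate 3. Sox9, the target of SRY, changed by -0.28 ± 0.14 (limma, adjusted p = 0.216), but its fall passed the threshold without control XY replicate 3 (limma, adjusted p = 0.0327). Fgf9 changed by -0.53 ± 0.28 (limma, adjusted p = 0.221) and Amh by -0.24 ± 0.38 (limma, adjusted p = 0.718).

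In the ovary pathway, 4 of 20 genes fell and 0 rose (7 and 0 adjusted over the list alone). Rspo1, which activates WNT signalling, fell by 1.12 ± 0.11 and Lef1 by 0.50 ± 0.10. Wnt4 changed by -0.09 ± 0.11 (limma, adjusted p = 0.630), Foxl2 by -0.53 ± 0.45 (0.478) and Fst by -0.08 ± 0.21 (0.832), and the signs for Wnt4 and Fst changed with the scaling. The ovary list had a camera adjusted p of 0.0706, which was 0.0283 without Dfo XY replicate 2, 0.0338 with no filter and 0.0234 without both Dfo libraries that held Xist. Of 18 genes of bipotential gonad somatic cells 7 fell and 1 rose (10 and 1 adjusted over the list alone), with Wt1 at -0.38 ± 0.08 and Gata6 up by 0.60 ± 0.11. This list had a camera adjusted p of 0.0192, with adjusted p = 0.398 with an estimated correlation and 0.0504 without Dfo XY replicate 1. Nr5a1 itself changed by -0.38 ± 0.14 (limma, adjusted p = 0.0778) and passed the threshold without E11.5 XX replicate 1 or 2 (0.0332 and 0.0329).

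Of 20 regulators of Sry, 5 rose and 4 fell (5 and 8 adjusted over the list alone), and the list did not differ from other genes (camera, adjusted p = 0.903). Its median and mean lay below 0 while the test pointed up. Kdm3a (chromosome 6, 71588972 to 71632990), the histone demethylase that acts on Sry, rose from 94.8 ± 8.15 to 298.4 ± 7.03 TPM (SD, n = 3), a log2 change of 1.65 ± 0.10 (limma, adjusted p = 8.38e-07). Cited2 rose by 1.14 ± 0.25. Of 27 JmjC and TET dioxygenases, enzymes that need iron, 11 rose and 1 fell (12 and 2 adjusted over the list alone), among them Jmjd6 by 1.60 ± 0.15 and Kdm4b by 1.26 ± 0.10. Kdm3a and Kdm4b also stand in the hypoxia list. For the dioxygenases camera gave an adjusted p of 8.72e-07, and adjusted p = 0.112 with an estimated correlation.

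Respiratory-chain genes were lower with Dfo. Of 74 nuclear-encoded respiratory subunits 31 fell and 0 rose (44 and 0 adjusted over the list alone), such as Ndufb7 by 0.85 ± 0.08 and Cox6c by 0.76 ± 0.08. This list lay -0.23 from all genes (camera, adjusted p = 1.22e-10; adjusted p = 0.0295 with an estimated correlation). Of 31 genes of haem synthesis and iron-sulfur assembly 10 fell and 2 rose, also adjusted over the list alone (10 and 2), with Glrx5 down (-0.70 ± 0.12) and Cpox up (1.03 ± 0.12). Its camera adjusted p was 0.0464, with adjusted p = 0.187 with an estimated correlation, 0.0852 without control XY replicate 2 and 0.302 without Dfo XY replicate 3. Of 36 mitosis genes 19 fell and 0 rose (21 and 0 adjusted over the list alone), with Ccnb2 at -1.59 ± 0.20 and Ube2c 2.14-fold lower (camera, adjusted p = 1.53e-08; adjusted p = 0.193 with an estimated correlation). Of 40 S-phase genes 1 rose and 2 fell (0 and 1 adjusted over the list alone), and the camera adjusted p was 0.238, at a distance of 0.15, although it was 0.0348 without control XY replicate 3 and 0.0168 without Dfo XY replicate 1. Without both Dfo libraries that held Xist the distance was 0.36 (camera, adjusted p = 1.82e-06). The median and mean of the S-phase list lay below 0 while the test pointed up.

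Some markers of other cell types of the dissected tissue were called too. In the coelomic epithelium list 6 of 12 genes fell (8 fell and 1 rose adjusted over the list alone), with Upk3b at -1.21 ± 0.19 and Aldh1a2 at -1.14 ± 0.10. In the mesenchyme list 9 of 18 fell (10 adjusted over the list alone), with Col1a1 at -0.94 ± 0.10. The germ cell list had 3 of 15 genes down, also adjusted over the list alone (3), with Ifitm1 at -1.18 ± 0.12. The mesonephric epithelium list had 4 of 15 down (7 adjusted over the list alone), and the neural crest and neuron list 3 of 16 down and 1 up (10 and 1 adjusted over the list alone), with Tubb3 at -1.79 ± 0.37. The camera adjusted p of these 5 lists were 0.00424, 0.000309, 0.0420, 0.0249 and 0.0496, and with an estimated correlation the adjusted p were 0.183, 0.164, 0.187, 0.398 and 0.402. Without Dfo XY replicate 3 the germ cell, mesonephric and neural lists had adjusted p of 0.334, 0.368 and 0.174. Without control XY replicate 2 the germ cell and neural lists had 0.0852 and 0.0852, and the neural list also ended its call without any of 6 further libraries, up to an adjusted p of 0.223 without control XY replicate 1.

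The erythroid and macrophage lists had no called member in 13 and 16 genes (limma, 0 also adjusted over the list alone). Hba-a1 changed by 0.68 ± 0.68 (limma, adjusted p = 0.553) and Fcer1g by 0.82 ± 0.42 (0.222). As lists they lay 0.76 and 0.48 above all genes (camera, adjusted p = 0.0249 and 0.0150), with adjusted p = 0.402 and 0.362 with an estimated correlation. Without control XY replicate 3 their adjusted p were 0.864 and 0.256, and without Dfo XY replicate 1 the erythroid list had 0.164. Among 19 endothelial genes 1 rose, Flt1 by 1.45 ± 0.23, and 1 fell, Ramp2 (-1.28 ± 0.21), with 1 and 1 adjusted over the list alone. The endothelial list had a camera adjusted p of 0.0795, and 0.00662, 0.0126 and 0.00152 without control XY replicate 1, control XY replicate 2 or Dfo XY replicate 3. Among 13 steroidogenic genes 1 rose and 2 fell (1 and 3 adjusted over the list alone; camera, adjusted p = 0.723), with Fdxr at -1.01 ± 0.21. In the list of Y-linked genes and Xist 1 of 6 genes rose, which was Xist with 2.84 ± 0.78 (limma, adjusted p = 0.0276; camera for the list, 0.713). The Xist call ended when any of 5 libraries was left out, up to an adjusted p of 0.109 without Dfo XY replicate 2.

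The largest increases were those of Ankrd37 (chromosome 8, 45996902 to 46005707), from 6.34 ± 4.08 to 169.4 ± 18.0 TPM (SD, n = 3), Sprr1a (4.53 ± 0.39), Ier3 (4.13 ± 0.29) and Ndrg1 (4.11 ± 0.31), followed by Ero1l, P4ha2, Cxcl10 (3.68 ± 0.32) and Slc2a1 (3.65 ± 0.18). After Sry, the largest decreases were those of Crabp2, a retinoic acid binding protein (88.2 ± 14.4 to 20.1 ± 4.38 TPM, SD, n = 3), Dppa5a (-2.08 ± 0.54), Apoc1 (-1.98 ± 0.39), Ppp1r14a (-1.96 ± 0.16), Gstt2 (-1.95 ± 0.37), Tmem119 (-1.94 ± 0.27) and Tagln3 (-1.92 ± 0.54). The call for Dppa5a ended without control XY replicate 1, control XY replicate 3 or Dfo XY replicate 3 (limma, adjusted p = 0.0753, 0.0830 and 0.0731). The call for Tagln3 ended when any of 4 libraries was left out, up to an adjusted p of 0.115 without control XY replicate 1.

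In all, 2498 of 16133 genes were called between Dfo XY and control XY, 803 higher and 1695 lower with Dfo, and 301 of the increases and 363 of the decreases were at least 2-fold. The median of all genes was -0.17, and the split depended on the scaling, with 1518 higher and 1024 lower after median-of-ratios scaling (median -0.05), 1291 and 1193 after quantile normalization, and 1177 and 1207 with the 50 most abundant genes left out. The count was 1533 without control XY replicate 1, 1547 without control XY replicate 2, 1598 without Dfo XY replicate 1 and 1490 without Dfo XY replicate 2. It was 850 with replicates 1 and 2 of each group averaged and 901 without both Dfo libraries that held Xist. Among the 28 lists, 21 were called and 6 remained with an estimated correlation, namely hypoxia response, glycolysis, integrated stress response, immediate early, cholesterol synthesis and nuclear-encoded respiratory subunits. Median-of-ratios scaling also ended the calls of the bipotential gonad, haem, erythroid and macrophage lists, and quantile normalization those of the germ cell and erythroid lists. With array weights the calls of the haem, germ cell, erythroid, macrophage and mesonephric lists ended (camera, adjusted p = 0.132, 0.107, 0.110, 0.126 and 0.195). At TPM of at least 5 those of the haem, germ cell, macrophage and neural lists ended (0.0954, 0.104, 0.0530 and 0.104). Leaving out the 50 most abundant genes ended the haem and erythroid calls (0.0561 and 0.112). The replicate block ended the haem, germ cell and neural calls (0.0703, 0.0619 and 0.0572). Some of these calls also ended under further alternatives. Leaving out both Dfo libraries that held Xist left 1 library in the Dfo group, assumed to vary like the other groups. Fewer calls are made from fewer libraries, and those for Lef1, Wt1, Gata6, Cited2 and Flt1 ended, with log2 changes of -0.50, -0.38, 0.60, 1.14 and 1.45 before and -0.49, -0.39, 0.47, 0.50 and 1.06 after (limma, adjusted p = 0.0821, 0.0715, 0.134, 0.359 and 0.103). The calls for Slc11a2, Pcbp1, Mybl1, Dppa5a and Tagln3 ended too, with log2 changes of -0.57, -0.35, 1.09, -2.08 and -1.92 before and -0.32, -0.43, 1.62, -2.76 and -2.73 after (limma, adjusted p = 0.377, 0.0906, 0.0540, 0.0697 and 0.0630). The bipotential gonad list went from a distance of -0.23 to -0.29 and the erythroid list from 0.76 to 0.06, and their calls ended (camera, adjusted p = 0.119 and 0.846), while the S-phase and ovary lists gained one.

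**Figure D2:**
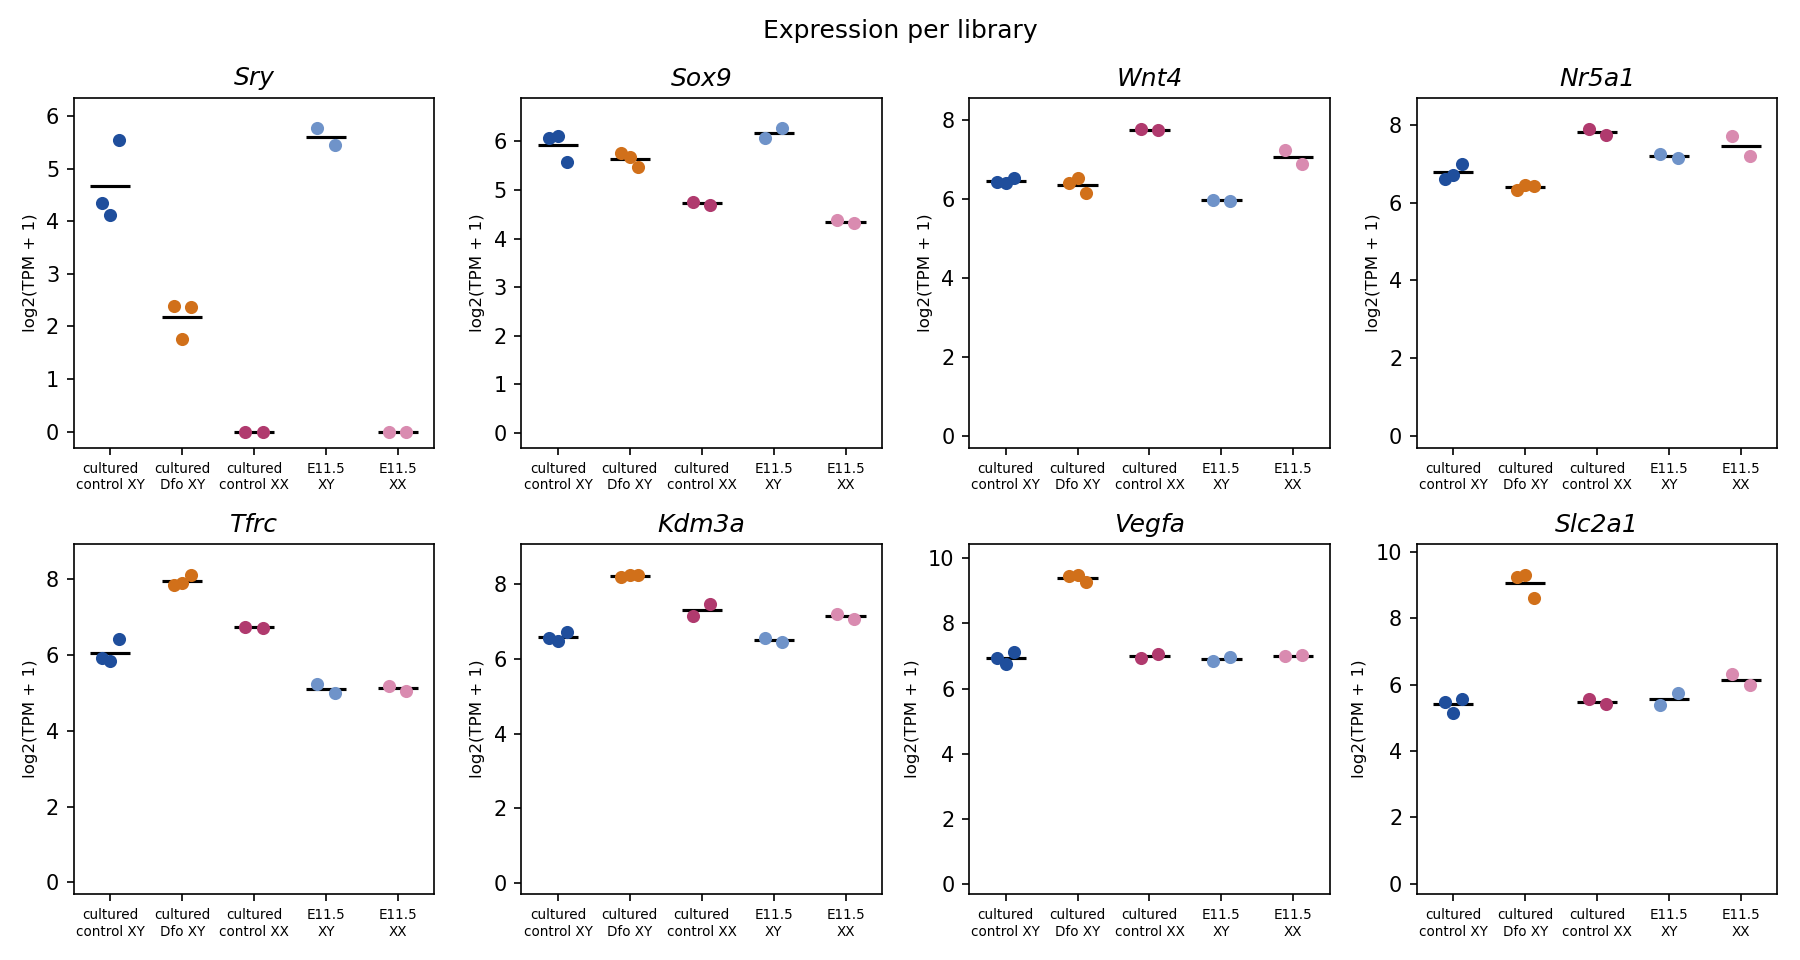
Expression of named genes per library as log2(TPM + 1), with 1 point per library in the 5 groups and lines for group means. Sry was listed at 0 in the 4 XX libraries and averaged 27.1 TPM in control XY and 3.60 TPM in Dfo XY, and Tfrc averaged 67.2 and 249.2 TPM in the same groups.

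The comparison of XY and XX at E11.5 gave the sex difference in cells not named as cultured. Sry and Sox9 were higher in XY, and Fos and the ovary pathway genes Fst and Wnt4 were higher in XX. Sry stood at 47.9 ± 7.74 TPM in XY (SD, n = 2) and was listed at 0 in XX. Sox9 (chromosome 11, 112782224 to 112787760) had 71.0 ± 6.82 TPM in XY and 19.3 ± 0.643 TPM in XX (SD, n = 2 each), a log2 difference of 1.82 ± 0.18. Fos (chromosome 12, 85473890 to 85477273) had 40.2 ± 2.67 TPM in XY and 443.6 ± 152.9 TPM in XX (SD, n = 2 each).

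Of 25 testis pathway genes 3 were higher in XY (4 adjusted over the list alone) and 0 lower, namely Sry, Sox9 and Cbln4 (1.93 ± 0.40). Camera gave an adjusted p of 0.0375, with adjusted p = 0.325 with an estimated correlation, and 0.111 and 0.125 without E11.5 XY replicate 2 or E11.5 XX replicate 2. The distance of 0.30 became -0.00071 with quantile normalization (adjusted p = 0.201), and the call also ended with median-of-ratios scaling, the 50 most abundant genes or short non-coding RNAs left out, no filter, the replicate block and only the libraries compared (0.0783, 0.0919, 0.0709, 0.109, 0.0642 and 0.0522). Of 20 ovary pathway genes 5 were lower in XY (10 adjusted over the list alone) and 0 higher. Fst, which binds activin, differed by -2.56 ± 0.26, Wnt4 by 2.14-fold, from 134.6 ± 22.8 TPM in XX to 61.9 ± 0.417 TPM in XY (SD, n = 2 each), the cell-cycle inhibitor gene Cdkn1b by -1.15 ± 0.13 and Foxl2 by -2.60 ± 0.55 (camera, adjusted p = 3.48e-07; adjusted p = 0.115 with an estimated correlation). The calls for Cbln4 and Foxl2 each ended when any of 6 libraries was left out, up to an adjusted p of 0.116 without E11.5 XX replicate 2 and 0.185 without E11.5 XX replicate 1. Fgf9 differed by 1.28 ± 0.34 (limma, adjusted p = 0.0627) and passed the threshold without control XY replicate 3 (limma, adjusted p = 0.0435). Amh (0.39 ± 0.47) and Nr5a1 (-0.26 ± 0.17) were not called (limma, adjusted p = 0.686 and 0.420).

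Of 23 immediate early genes 16 were lower in XY and 0 higher (20 and 0 adjusted over the list alone), with Fosb at -2.89 ± 0.15, Junb at -2.11 ± 0.22 and Jun at -1.50 ± 0.16. Nr4a1 (-2.76 ± 0.35) and Klf4 (-2.65 ± 0.31) were among the largest decreases. This list lay -1.63 from all genes (camera, adjusted p = 5.21e-26), with adjusted p = 0.0523 with an estimated correlation. Of 30 genes of the integrated stress response 5 were lower in XY and 0 higher (7 and 0 adjusted over the list alone), such as Ppp1r15a at -1.09 ± 0.13 (camera, adjusted p = 8.75e-05; adjusted p = 0.115 with an estimated correlation). Mesonephric epithelium genes, of which 0 of 15 were called in limma (6 higher in XY adjusted over the list alone), lay 0.78 above all genes (camera, adjusted p = 4.42e-05; adjusted p = 0.262 with an estimated correlation). Endothelial genes lay -0.61 from all genes, steroidogenic genes -0.58 and erythroid genes 0.85, with 0 of 19, 1 of 13 (lower in XY) and 0 of 13 genes called in limma, the same counts as adjusted over the list alone. Their camera adjusted p were 0.00254, 0.0135 and 0.0310, and with an estimated correlation the adjusted p were 0.535, 0.262 and 0.535. These calls ended without E11.5 XY replicate 2 (0.0644), E11.5 XY replicate 1 (0.0821) and E11.5 XX replicate 1 (0.141), and the erythroid call also with median-of-ratios scaling, quantile normalization, no trend and the 50 most abundant genes left out (0.0742, 0.105, 0.0602 and 0.0533). The largest increases besides Sry were those of Gtsf1l, Rtbdn, Gpr15, Ifna1 and Sst, with Gtsf1l at 9.61 ± 0.856 TPM and Rtbdn at 5.81 ± 1.08 TPM in XY (SD, n = 2) and both listed at 0 in XX. The decreases included H2-L and Ifi27l2a, which had 6.98 ± 3.57 TPM in XX (SD, n = 2) and was listed at 0 in XY. Leaving out E11.5 XX replicate 1 ended the calls for Gtsf1l, Rtbdn, Gpr15, Ifna1, Sst, Ifi27l2a and H2-L (limma, adjusted p = 0.132, 0.0688, 0.212, 0.201, 0.121, 0.0838 and 0.153), and all of these except Rtbdn and Ifi27l2a also ended without other libraries. Ifna1 and H2-L belong to families of near-identical genes.

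In all, 370 genes were called at E11.5, 176 higher and 194 lower in XY, with a median of 0.00 over all genes. The split depended on the filter, with 60 higher and 168 lower at TPM of at least 5, and 349 and 216 with no filter. The count was 30 with only these 4 libraries in the fit. Leaving out 1 of these libraries gave 152, 140, 53 and 161 calls, for E11.5 XY replicates 1 and 2 and E11.5 XX replicates 1 and 2. The spread is shared over all groups, so libraries of other groups moved the count too, to 190, 159 and 636 without control XY replicates 1, 2 or 3 and to 176 and 174 without Dfo XY replicates 1 or 2. Of the 28 lists 14 were called, or 9 without E11.5 XY replicate 2, and 0 with an estimated correlation (camera). The Wnt4 call ended with only these 4 libraries in the fit.

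Between control XY and control XX in culture, Sry and Sox9 were higher in XY, and Wnt4, Nr5a1, 13 of 18 bipotential gonad genes and 20 of 24 cholesterol synthesis genes were lower. No list kept its camera call with an estimated correlation (lowest adjusted p = 0.0988). Sry stood at 27.1 ± 16.0 TPM (SD, n = 3) in XY and was listed at 0 in XX. Sox9 had 60.4 ± 11.8 TPM in XY (SD, n = 3) and 25.4 ± 0.813 TPM in XX (SD, n = 2), and Wnt4 (chromosome 4, 137277489 to 137299726) 87.2 ± 4.92 and 217.2 ± 4.43 TPM. Nr5a1 (chromosome 2, 38692656 to 38714542) had 109.7 ± 15.7 TPM in XY and 225.6 ± 18.8 TPM in XX, a log2 difference of -1.04 ± 0.15 (limma, adjusted p = 0.00118).

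Of 18 genes of bipotential gonad somatic cells 13 were lower in XY and 0 higher (14 and 0 adjusted over the list alone), among them Podxl (-1.27 ± 0.14), Gata6 (-0.91 ± 0.13) and Wt1 (-0.79 ± 0.08). Of 20 ovary pathway genes 9 were lower and 1 higher (10 and 1 adjusted over the list alone), such as Runx1 (-1.13 ± 0.18) and Lef1 (-0.91 ± 0.11). The testis pathway had 3 genes higher and 3 lower of 25 (3 and 4 adjusted over the list alone), with Inhbb at -1.06 ± 0.16. The camera adjusted p of these lists were 2.32e-05, 0.0209 and 0.00389, and with an estimated correlation the adjusted p were 0.155, 0.378 and 0.141. The ovary list had 0.0608 without control XY replicate 3, and 0.0853, 0.0797 and 0.0637 at TPM of at least 5, with the replicate block and with only the libraries compared, and the testis list had 0.0713 with quantile normalization. Of 24 cholesterol synthesis genes 20 were lower in XY and 0 higher (22 and 0 adjusted over the list alone), with Cyp51 at -0.91 ± 0.09 (camera, adjusted p = 3.53e-09; adjusted p = 0.155 with an estimated correlation). Of 22 genes of the unfolded protein response 16 were lower (17 adjusted over the list alone), with Hyou1 at -0.99 ± 0.11 and Calr at -0.67 ± 0.10 (camera, adjusted p = 6.99e-06; adjusted p = 0.141 with an estimated correlation). Tfrc differed by -0.67 ± 0.15, a call that ended without control XX replicate 1 (limma, adjusted p = 0.0573), and Kdm3a by -0.73 ± 0.11. Fgf9, Amh and Foxl2 were not called (limma, adjusted p = 0.683, 0.197 and 0.580). Fst differed by -0.95 ± 0.24, a call that ended without control XY replicate 1, control XX replicate 1 or control XX replicate 2 (limma, adjusted p = 0.0554, 0.0662 and 0.0701).

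Some markers of other cell types were higher in cultured XY than in cultured XX. Of 16 neural crest and neuron genes 12 were higher and 0 lower, also adjusted over the list alone (12 and 0), with Stmn2 at 2.43 ± 0.41 and Gap43 at 1.69 ± 0.31. Of 15 mesonephric epithelium genes 11 were higher and 0 lower, also adjusted over the list alone (11 and 0), with Epcam at 1.66 ± 0.22 and Ret at 1.64 ± 0.33. Of 16 macrophage and leukocyte genes 5 were higher (7 adjusted over the list alone), with Coro1a at 1.70 ± 0.30 and Tyrobp at 14.7 ± 11.2 TPM in XY (SD, n = 3) and listed at 0 in XX. Of 13 erythroid genes 4 were higher (5 adjusted over the list alone), with Hba-a1 at 4.55 ± 0.76 and Hbb-bh1 at 2.68 ± 0.49. Globins took 0.220% and 0.252% of TPM in control XY replicates 1 and 2, 0.0325% in control XY replicate 3, and 0.0261% and 0.0233% in the cultured XX libraries. The camera adjusted p of these 4 lists were 2.34e-11, 5.24e-10, 1.50e-07 and 1.60e-05, and with an estimated correlation the adjusted p were 0.0988, 0.104, 0.141 and 0.155. Of 15 germ cell genes 1 was higher and 1 lower (0 and 1 adjusted over the list alone), and of 19 endothelial genes 2 were higher and 0 lower (0 and 0 adjusted over the list alone). These lists lay 0.55 and 0.53 above all genes (camera, adjusted p = 0.00994 and 0.00194; adjusted p = 0.141 and 0.532 with an estimated correlation), and the germ cell call ended with median-of-ratios scaling, quantile normalization and TPM of at least 5 (adjusted p = 0.0630, 0.598 and 0.112). The mesenchyme list had 2 of 18 genes higher and 5 lower (3 and 5 adjusted over the list alone). The coelomic epithelium list had 0 of 12 higher and 3 lower and the steroidogenic list 0 of 13 higher and 3 lower, each also adjusted over the list alone (0 and 3). These 3 lists were not called (camera, adjusted p = 0.940, 0.809 and 0.940). Other large differences were those of Pard3b (-2.68 ± 0.23) and Ibsp (-2.14 ± 0.40), and Ifi27l2a had 10.4 ± 3.59 TPM in XY (SD, n = 3) and was listed at 0 in XX. The calls for Hotairm1, Snora23, Tsacc, Lrch4 and Lars2 ended without control XX replicate 1 (limma, adjusted p = 0.0837, 0.213, 0.136, 0.135 and 0.123) and without other libraries too, and that for Smim24 without control XX replicate 2 (0.0989).

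In all, 4064 genes were called between control XY and control XX in culture, 479 higher and 3585 lower in XY, with a median of -0.22 over all genes. After median-of-ratios scaling 528 were higher and 490 lower (median 0.07), after quantile normalization 291 and 323, with the 50 most abundant genes left out 513 and 735, and with short non-coding RNAs left out 528 and 1053. The median-of-ratios factors were 0.93, 0.93 and 1.01 in control XY and 1.20 and 1.22 in control XX. Dividing by them moves the log2 difference of each gene upward. Negative differences such as those of Tfrc, Kdm3a and Nr5a1 then become smaller in size. The count was 2311 without control XY replicate 1, 2311 without control XY replicate 2, 1920 without control XX replicate 1 and 2279 without control XX replicate 2. Of the 28 lists 20 were called and 0 with an estimated correlation (camera).

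The interaction asked whether the sex difference in culture differed from that at E11.5. Fos and Fosb were lower in XY by less in culture than at E11.5 (2.05 ± 0.25 and 1.87 ± 0.21; limma, adjusted p = 0.00423 and 0.00304). Cholesterol synthesis genes differed the other way, with Lss at -1.34 ± 0.17 and Cyp51 at -1.03 ± 0.13 (limma, adjusted p = 0.00423 and 0.00605). Of the 24 genes of that list 10 were lower and 0 higher (22 and 0 adjusted over the list alone; camera, adjusted p = 1.59e-14; adjusted p = 0.116 with an estimated correlation). Sox9 had an interaction of -0.62 ± 0.24 (limma, adjusted p = 0.166). The lists whose interaction held with an estimated correlation were immediate early, germ cells and neural crest and neurons (adjusted p = 0.0445 for each). In all, 215 genes had a called interaction, 31 higher and 184 lower. The count was 34, 53 and 41 after median-of-ratios scaling, after quantile normalization and without the 50 most abundant genes, with 21, 29 and 21 of them higher. Leaving out control XY replicates 1, 2 or 3 gave 19, 18 and 731 calls, Dfo XY replicates 1, 2 or 3 gave 41, 48 and 454, control XX replicates 1 or 2 gave 24 and 45, E11.5 XY replicates 1 or 2 gave 19 and 47, and E11.5 XX replicate 2 gave 14. With replicates 1 and 2 of the cultured XY groups averaged 7 genes were called, and the calls for Lss and Cyp51 ended. Of the 28 lists 17 were called, or 11 without E11.5 XY replicate 1.

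Across 16127 genes the sex difference in culture correlated with that at E11.5 with r = 0.38 (Spearman 0.38), and across the 365 genes called at E11.5 with r = 0.62 (Spearman 0.65). The first value was 0.24 without E11.5 XY replicate 2. Across genes the Dfo effect correlated with the E11.5 sex difference with r = -0.09 over 16127 genes (Spearman -0.10) and -0.24 over the 365 (Spearman -0.17). Genes are not independent replicates, 5 such relations were computed, and the effects correlated share no library. Of 172 genes higher in XY at E11.5, 4 rose and 13 fell under Dfo, with a distance of -0.05 from all genes (camera, p = 0.266; p = 0.680 with an estimated correlation). Of 193 genes higher in XX at E11.5, 40 rose and 47 fell, with a distance of 0.06 (camera, p = 0.341; p = 0.730 with an estimated correlation). When a library was left out, both lists were drawn again from that fit. Their genes then differ from these 172 and 193. The XY-biased genes passed the threshold downward without control XY replicate 1 or E11.5 XX replicate 2, at distances of -0.20 and -0.15. The XX-biased genes passed it upward without any 1 of 7 libraries, with the largest distance, 0.93, without E11.5 XX replicate 1.

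Control culture was compared with E11.5 to show how cultured cells differed from cells labelled with that stage. In XY, genes of cholesterol synthesis, of the integrated stress response and of neural crest and neurons were higher in culture. The sterol oxidase gene Msmo1 (chromosome 8, 64718139 to 64733792) had 273.5 ± 9.90 TPM in culture (SD, n = 3) and 50.3 ± 9.18 TPM at E11.5 (SD, n = 2). The membrane glycoprotein gene Gpnmb (chromosome 6, 49036546 to 49070929) had 36.3 ± 13.1 and 0.125 ± 0.177 TPM. Tfrc had 67.2 ± 14.99 and 33.8 ± 3.73 TPM, a log2 difference of 0.95 ± 0.15 (limma, adjusted p = 0.00470).

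Of 24 cholesterol synthesis genes 22 were higher in cultured XY and 0 lower, also adjusted over the list alone (22 and 0), with Fdps at 2.04 ± 0.09 and Lss at 2.01 ± 0.11. Of 30 genes of the integrated stress response 12 were higher and 0 lower (17 and 0 adjusted over the list alone), such as Trib3 (2.13 ± 0.29) and Asns (1.02 ± 0.13). Of 16 neural crest and neuron genes 10 were higher and 0 lower (15 and 0 adjusted over the list alone), with Tubb3 at 2.54 ± 0.41 and Gap43 at 2.40 ± 0.31. These 3 lists had camera adjusted p of 7.05e-47, 6.21e-16 and 7.16e-17, and with an estimated correlation the adjusted p were 0.0136, 0.0136 and 0.0208. Of 36 mitosis genes 23 were lower and 0 higher (34 and 0 adjusted over the list alone), such as Mki67 (-0.79 ± 0.12), and 10 of 23 immediate early genes were higher (12 higher and 1 lower adjusted over the list alone), such as Fos (1.52 ± 0.17) and Egr1 (1.44 ± 0.20). Their camera adjusted p were 2.49e-18 and 1.89e-09, and the adjusted p with an estimated correlation was 0.124 for each. The macrophage list had 4 of 16 genes higher (6 adjusted over the list alone), with Lyz2 at 3.65 ± 0.33 and C1qb at 2.21 ± 0.31 (camera, adjusted p = 9.38e-09; adjusted p = 0.113 with an estimated correlation). The endothelial list had 4 of 19 lower (5 adjusted over the list alone), with Kdr at -1.16 ± 0.14 (camera, adjusted p = 0.000225; adjusted p = 0.537 with an estimated correlation, 0.150 without control XY replicate 3, 0.0513 with the replicate block and 0.0602 with array weights).

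Other large differences in XY were those of Celf3 (3.76 ± 0.46), Lgals3 (3.75 ± 0.49) and Aplnr (-3.01 ± 0.24). Rps27 differed by 6.95 ± 1.13, but it shares reads with near-identical copies and its value is uncertain. The calls for Ptgds, Nrn1l, Fgf2, Ifna1, Gtsf1l and Rpl10l ended without E11.5 XY replicate 1 (limma, adjusted p = 0.141, 0.0964, 0.122, 0.165, 0.110 and 0.106), and all of these except Nrn1l also without other libraries. Sox9, Nr5a1, Sry and Kdm3a were not called (limma, adjusted p = 0.377, 0.118, 0.156 and 0.762), but Sry and Nr5a1 were lower in culture without control XY replicate 3 (0.0185 and 0.0489). In all, 913 genes were called, 422 higher and 491 lower in culture, with a median of -0.11. After median-of-ratios scaling 617 were higher and 422 lower, after quantile normalization 737 and 518, and without the 50 most abundant genes 669 and 320. The count was 283, 279 and 1489 without control XY replicates 1, 2 or 3, and 275 and 478 without E11.5 XY replicates 1 or 2. It was 427 with only these 5 libraries in the fit.

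In XX, cultured cells had 468.8 ± 24.9 TPM of Msmo1 and E11.5 cells 47.8 ± 0.530 TPM (SD, n = 2 each). Of 24 cholesterol synthesis genes 23 were higher in culture and 0 lower (24 and 0 adjusted over the list alone), with Lss at 3.35 ± 0.12 and Fdps at 2.91 ± 0.10 (camera, adjusted p = 2.91e-46; adjusted p = 0.0283 with an estimated correlation). Tfrc had 105.8 ± 1.32 and 34.0 ± 2.34 TPM (SD, n = 2 each), a log2 difference of 1.61 ± 0.17 (limma, adjusted p = 0.000149). In the iron handling list 5 of 23 genes were higher and 0 lower (8 and 0 adjusted over the list alone), with Slc40a1, the iron exporter, at 1.07 ± 0.19 and Slc11a2 at 1.02 ± 0.17 (camera, adjusted p = 0.0676).

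Of 19 endothelial genes 12 were lower in cultured XX (17 adjusted over the list alone), with Esam at -2.33 ± 0.30 and Kdr at -1.27 ± 0.16 (camera, adjusted p = 4.58e-20; adjusted p = 0.116 with an estimated correlation). Of 13 erythroid genes 5 were lower (6 adjusted over the list alone), with Hba-a1 at -4.73 ± 0.84 (camera, adjusted p = 9.12e-06; adjusted p = 0.231 with an estimated correlation). Of 23 immediate early genes 7 were lower (10 adjusted over the list alone), with Fosb at -1.22 ± 0.15 (camera, adjusted p = 1.17e-08; adjusted p = 0.146 with an estimated correlation). Of 30 genes of the integrated stress response 15 were higher and 2 lower (17 and 2 adjusted over the list alone), with Asns at 1.11 ± 0.14, and of 22 genes of the unfolded protein response 8 were higher (11 adjusted over the list alone), with Hyou1 at 0.75 ± 0.12. Their camera adjusted p were 1.89e-05 and 5.37e-07, and with an estimated correlation the adjusted p were 0.116 and 0.146. Wnt4 was higher by 0.70 ± 0.14, a call that ended without control XX replicate 1 or E11.5 XX replicate 2 (limma, adjusted p = 0.0643 and 0.0964). Fst was lower (-1.08 ± 0.26), a call that ended without any 1 of the 4 libraries compared, up to an adjusted p of 0.117 without E11.5 XX replicate 1. Kdm3a was not called (limma, adjusted p = 0.480), and Nr5a1 (0.204) passed the threshold only without E11.5 XX replicate 1 (0.0356).

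Large differences in XX included those of Gpnmb (4.40 ± 0.32), Scd1 (3.94 ± 0.20), Sst (3.28 ± 0.55), Aplnr (-3.17 ± 0.26) and Rhox9 (-3.02 ± 0.39), and Lgals3 had 15.97 ± 1.41 TPM in culture (SD, n = 2) and was listed at 0 at E11.5. The calls for Tsacc, Snora23 and Hotairm1 ended without any 1 of the 4 libraries compared, except that Snora23 kept its call without control XX replicate 2 (limma, highest adjusted p = 0.131, 0.300 and 0.0650). In all, 1463 genes were called, 1187 higher and 276 lower in culture, with a median of 0.12. After median-of-ratios scaling 475 were higher and 378 lower, after quantile normalization 426 and 278, and without the 50 most abundant genes 695 and 289. The count was 570 and 784 without control XX replicates 1 or 2 and 432 without E11.5 XX replicate 2.

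Dfo XY was also compared with control XX in culture, which set the cells with lowered Sry beside cells that lack it. There was no Dfo XX group, so the effects of sex and of Dfo cannot be told apart within this comparison. Sry remained at 3.60 ± 1.04 TPM in Dfo XY (SD, n = 3) and was listed at 0 in XX. Sox9 had 49.0 ± 5.17 TPM in Dfo XY (SD, n = 3) and 25.4 ± 0.813 TPM in XX (SD, n = 2), a log2 difference of 0.92 ± 0.16 (limma, adjusted p = 0.000833). Wnt4 (82.0 ± 10.7 and 217.2 ± 4.43 TPM), Lef1 (-1.41 ± 0.11) and Rspo1 (-1.48 ± 0.13) were lower in Dfo XY, and Nr5a1 was lower by a log2 difference of -1.42 ± 0.15. Fst differed by -1.03 ± 0.24. Tfrc (1.22 ± 0.15), Vegfa (2.40 ± 0.11) and Kdm3a (0.92 ± 0.11) were higher.

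Of 39 hypoxia-response genes 32 were higher in Dfo XY and 4 lower (32 and 5 adjusted over the list alone), with P4ha2 at 4.09 ± 0.22, and of 30 genes of the integrated stress response 20 were higher and 3 lower (20 and 4 adjusted over the list alone). Their camera adjusted p were 5.98e-39 and 9.52e-18, and with an estimated correlation the adjusted p were 0.0178 and 0.0101. Of 20 ovary pathway genes 11 were lower and 0 higher (12 and 0 adjusted over the list alone), and of 18 bipotential gonad genes 13 were lower and 0 higher (15 and 0 adjusted over the list alone). Their camera adjusted p were 0.00424 and 1.03e-05, and with an estimated correlation the adjusted p were 0.272 and 0.153. Markers of some other cell types were higher in Dfo XY, with 6 of 13 erythroid, 9 of 16 macrophage, 4 of 15 mesonephric, 4 of 16 neural crest and neuron and 4 of 19 endothelial genes (6, 9, 2, 4 and 4 adjusted over the list alone), and 1 endothelial gene was lower (1 adjusted over the list alone). These lists lay 1.60, 1.55, 0.93, 0.73 and 0.63 above all genes, with camera adjusted p of 3.70e-07, 3.79e-10, 3.28e-05, 8.81e-06 and 0.000205, and with an estimated correlation the adjusted p were 0.143, 0.0604, 0.153, 0.143 and 0.369. Without both Dfo libraries that held Xist the mesonephric and endothelial calls ended (adjusted p = 0.104 and 0.196). Mesenchyme genes were lower, 11 of 18 (12 adjusted over the list alone; camera, adjusted p = 0.0167; adjusted p = 0.331 with an estimated correlation), a call that ended with TPM of at least 5, the replicate block or only the libraries compared (0.169, 0.0630 and 0.0754). The germ cell, coelomic epithelium and steroidogenic lists were not called (camera, adjusted p = 0.532, 0.0573 and 0.747). Other large differences were those of Hba-a1 (5.23 ± 0.76), Sprr1a (4.09 ± 0.44), Ibsp (-3.14 ± 0.40), Aldh1a1 (-3.13 ± 0.41) and Cryge (-3.03 ± 0.57). Cox4i2 and Ifit3 had 34.1 ± 10.3 and 15.3 ± 7.07 TPM in Dfo XY (SD, n = 3) and were listed at 0 in XX, and Smim24 had 10.2 ± 5.23 TPM in XX (SD, n = 2) and was listed at 0 in Dfo XY. The calls for Snora23, Amd1 and Tsacc ended without control XX replicate 1 (limma, adjusted p = 0.113, 0.0829 and 0.0678). In all, 6234 genes were called, 773 higher and 5461 lower in Dfo XY, with a median of -0.33. After median-of-ratios scaling 1775 were higher and 1409 lower (median 0.07), after quantile normalization 1378 and 1571, and without the 50 most abundant genes 1358 and 2048. The count was 2967 without both Dfo libraries that held Xist. Of the 28 lists 18 were called and 2 with an estimated correlation (camera).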

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

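The interaction between sex and culture was planned before the data were examined, and the tests of explanations in this part were chosen after their results were seen. The genes and lists in the next paragraphs stand here because their sex difference in culture differed from that at E11.5 in the limma or camera test of the difference itself. Most of the gene calls ended under several alternatives, and those for Junb, Ier2, Fdps, Gap43, Dbh, Lyz2, C1qb, Cbln4, Fst and Wt1 each ended when any 1 of at least 4 libraries was left out, with the highest adjusted p at 0.162 for Cbln4 without E11.5 XX replicate 2.

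For immediate early genes the interactions were 2.05 for Fos, 1.87 for Fosb, 1.92 for Junb and 1.49 for Ier2 (limma, adjusted p = 0.00423, 0.00304, 0.0208 and 0.0316). For cholesterol synthesis they were -1.34 for Lss, -1.03 for Cyp51 and -0.87 for Fdps (limma, adjusted p = 0.00423, 0.00605 and 0.0208). For markers of neural crest and macrophages they were 2.86 for Gap43, 1.98 for Dbh, 2.55 for Lyz2 and 2.10 for C1qb (limma, adjusted p = 0.0208, 0.0364, 0.0326 and 0.0488). For gonad genes they were -2.48 for Cbln4, 1.61 for Fst and -0.59 for Wt1 (limma, adjusted p = 0.0479, 0.0488 and 0.0460).

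As lists, measured as the median interaction minus that of all genes, the largest were immediate early (1.39), neural crest and neurons (1.31), macrophages and leukocytes (1.25), germ cells (1.25) and endothelial cells (1.06). Erythroid cells (0.64), mesonephric epithelium (0.56), the integrated stress response (0.33), the ovary pathway (0.16) and steroidogenic cells (0.10) also lay above all genes. Cholesterol synthesis (-0.61), the JmjC and TET dioxygenases (-0.27), the unfolded protein response (-0.22), bipotential gonad cells (-0.21), S phase (-0.14), mitosis (-0.13) and Sry regulators (-0.0928) lay below. The calls of the erythroid, steroidogenic, S phase, mitosis and Sry regulator lists ended with median-of-ratios scaling (adjusted p = 0.128, 0.146, 0.0934, 0.115 and 0.0830) and with quantile normalization, and some under further alternatives. That of the ovary list ended with a pseudocount of 0.1 or no filter (0.0627 and 0.0687). With an estimated correlation only immediate early, neural crest and germ cells had an adjusted p under the threshold (0.0445 for each).

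Most genes called in culture were lower in the libraries with more Rpph1, and a candidate explanation is a larger share of TPM from short non-coding RNAs. With these RNAs left out, 50.1% of the calls under Dfo were lower, beside 67.9% before, but the median of all genes moved only from -0.17 to -0.10. Between cultured XY and XX 66.6% of the calls were still lower in XY, beside 88.2% before, but the median went from -0.22 to 0.00083. Median-of-ratios scaling gave 528 higher and 490 lower, but it centres the libraries on each other whatever the cause and so cannot decide. Leaving these RNAs out took the lower calls from 1695 to 1196 under Dfo and from 3585 to 1053 between cultured XY and XX. The higher calls went from 803 to 1192 and from 479 to 528. The number of lower calls thus depended on whether these RNAs were kept. The share of calls and the median point different ways in both comparisons, which leaves the explanation open as the whole cause. Why Rpph1 differed between the groups stays open, and no biological explanation was tested.

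Xist stood at 13.6 and 24.6 TPM in Dfo XY replicates 1 and 2, which is 7.97% and 14.4% of its level in cultured XX, and at 0.28 TPM in Dfo XY replicate 3. If RNA or cells of XX gonads were the source, their 4 Y-linked genes measured would be lower by -0.17 on the log2 scale. The measured difference was 0.0523 ± 0.279 (SE over the 4 genes, not over libraries), an error too wide to decide. Only 1 gene, Xist itself, had at least 20 TPM in cultured XX and at most 1 TPM in the 6 XY libraries without Xist. Smim24, with 10.2 TPM in cultured XX, was listed at 0 in Dfo XY, but 1 gene of this level decides nothing. Admixture and expression of Xist in XY cells under Dfo cannot be told apart for these libraries, the latter untested.

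Against cultured XX, 6 lists of markers of other cell types lay above all genes in cultured XY and the bipotential gonad list lay below, while the mesenchyme (0.05), coelomic epithelium (-0.07) and steroidogenic (-0.38) lists were not called (camera). A lower share of NR5A1(+) cells would raise the other types alike only if these entered in a fixed mix. All 6 list means were above 0, from 0.39 ± 0.38 for endothelial cells to 1.27 ± 0.24 for neural crest and neurons (log2, SE over libraries). The 6 lists were taken because they lay above all genes in this same comparison, so means above 0 give no support. The mean changes of the germ cell and mesonephric lists differed by -0.61 ± 0.10, the clearest of 15 such differences. This cannot decide, because the mix is unknown and log2(TPM + 1) understates changes of genes with low values. A lower share and a change within a single cell type both stay open. A sex difference present at E11.5 too would give the lists like differences at that stage. The mean change of the 6 lists of other cell types was 0.97 ± 0.40 larger in culture than at E11.5. Taking the lists by their higher level in cultured XY enlarges this difference, so it cannot decide. At E11.5 their mean change was -0.03 ± 0.29, although the mesonephric list already differed by 0.65 ± 0.25 at that stage. The bipotential list differed in its mean by -0.52 ± 0.07 in culture and -0.32 ± 0.08 at E11.5, a difference of -0.19 ± 0.11 that camera called (adjusted p = 0.00551, but adjusted p = 0.379 with an estimated correlation and 0.0572 without E11.5 XY replicate 1). At E11.5 only 1 of its 18 genes was called, and the camera adjusted p of 0.0142 became 0.178 without E11.5 XY replicate 2, 0.0858 without E11.5 XX replicate 1 and, the highest of its alternatives, 0.510 with an estimated correlation, so a sex difference of the NR5A1(+) cells at both stages stays open for this list.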

How the results depend on the processing

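The alternatives chosen after the data were seen were leaving out short non-coding RNAs, averaging replicates 1 and 2 of each cultured XY group, and leaving out both Dfo libraries that held Xist. No named gene that was called changed direction under any alternative run, while some that were not called, such as Wnt4 and Fst under Dfo, changed sign with the scaling. Outside the fits that left out 1 library, 3285 gene results kept their side of the threshold, 311 lost their call and 7 gained one, and when 1 library was left out the numbers were 2589, 296 and 7. The depth is unknown, so sampling noise at low TPM was not separated from other spread. A group left with 1 library, whether E11.5, control XX or Dfo XY, was assumed to vary like the others.

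The 2498 calls under Dfo became 5763 with array weights, 850 with replicates 1 and 2 averaged and 901 without both Dfo libraries that held Xist, where fewer libraries were compared. With 1 library left out they ranged from 1490 to 2670. Of the 21 lists called, 6 held with an estimated correlation.

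The 4064 calls between cultured XY and XX became 1018 with median-of-ratios scaling, 614 with quantile normalization, 1248 without the most abundant genes, 1581 without short non-coding RNAs and 1774 with replicates averaged, and ranged from 1920 to 4352 with 1 library left out. In this comparison the nuclear-encoded respiratory list had a distance of 0.25 from all genes (camera, adjusted p = 0.0128). Its mean log2 change was -0.0072, and fry, which tests a list against no change and not against other genes, pointed down (adjusted p = 0.679). The mitosis list went from -0.08 to 0.10 with quantile normalization. The cause was not tested.

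The 370 calls at E11.5 became 565 with no filter, 228 at TPM of at least 5, 88 with array weights, 30 with only the libraries compared, 94 with replicates averaged and 104 without both Dfo libraries that held Xist, and ranged from 53 to 636 with 1 library left out. The 913 calls between cultured and E11.5 XY became 1454 with array weights, 427 with only the libraries compared and 195 with replicates averaged, and ranged from 275 to 1489. The 1463 calls in XX became 853 with median-of-ratios scaling, 704 with quantile normalization, 945 with no trend, 671 with only the libraries compared and 857 with replicates averaged, and ranged from 432 to 1682. The cause was not tested, apart from fewer libraries giving less information.

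The 6234 calls between Dfo XY and cultured XX became 3184 with median-of-ratios scaling, 2949 with quantile normalization, 3406 without the most abundant genes, 3665 without short non-coding RNAs and 2967 without both Dfo libraries that held Xist. The 215 interactions became 325 at TPM of at least 5, 34 with median-of-ratios scaling, 53 with quantile normalization, 41 without the most abundant genes, 44 without short non-coding RNAs, 61 with no trend, 327 with array weights, 20 with only the libraries compared, 7 with replicates averaged and 20 without both Dfo libraries that held Xist, and ranged from 14 to 731. The cause was not tested.

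With the replicate block, the replicate number as a further term, 3043 genes were called under Dfo, 971 at E11.5, 2592 between cultured and E11.5 XY and 1758 for the interaction. Only the control XY and Dfo XY numbers passed the correlation taken as pairing, without telling replicates 1 and 2 apart, and the other groups share no more than a number.

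The distance of the E11.5 XY-biased genes under Dfo passed the threshold at -0.15 with TPM of at least 5, -0.12 with median-of-ratios scaling, -0.14 with array weights and -0.31 with replicates averaged, and ranged from -0.20 to 0.11 with 1 library left out. In fry, which tests these genes against no change and not against other genes, p was 0.0323, beside 0.266 in camera for their distance of -0.0474. That of the XX-biased genes passed it at 0.45 with array weights and 0.44 with replicates averaged, and ranged from 0.0256 to 0.93. Alternatives that changed the fit drew both lists again from their own E11.5 calls. Array weights gave 36 genes higher and 52 lower in XY at E11.5, and averaging gave 39 and 55. The reported fit gave 176 and 194, so the lists compared differ. The correlation across genes of the Dfo effect with the E11.5 sex difference, -0.09, was 0.0374 without both Dfo libraries that held Xist. The correlation of the 2 sex differences, 0.38, was 0.21 with quantile normalization and ranged from 0.24 to 0.41. The cause was not tested.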

Other observations

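The tests of the explanations for Tfrc and Sry were chosen after the results were seen. Among genes outside the fixed lists, Cxcl10, a chemokine gene, rose under Dfo by 3.68 ± 0.32 and Sprr1a by 4.53 ± 0.39 (limma, adjusted p = 9.97e-06 for each), and Crabp2 fell by 2.09 ± 0.17 (limma, adjusted p = 5.64e-06). Ifit3, induced by interferon, had 15.3 ± 7.07 TPM in Dfo XY (SD, n = 3) and was listed at 0 in cultured XX (limma, adjusted p = 5.05e-05). These 2 groups differ in sex as well as in Dfo.

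The 6 cultured XY libraries can be split into groups of 3 in 10 ways, too few for a share under 0.05. The real split gave 2498 calls, and 1 split, the real one, gave as many. The highest of the others was 0 calls (limma), with 120 to 1207 genes at an unadjusted p under 0.05 beside 4755 in the real split. The 3 other splits that part all libraries of equal number gave 0 calls each, with 132 to 273 genes at an unadjusted p under 0.05. Every split but the real one puts control and Dfo libraries together in each group. An effect of Dfo would then widen the spread within groups and lower the calls. The 0 calls thus do not show how many would be called without an effect.

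Tfrc was higher in cultured control cells than at E11.5 in each sex, and a candidate explanation is that the culture itself limits iron and shifts genes as Dfo does. In cultured XX against E11.5 XX, which share no library with the Dfo comparison, the 803 genes raised by Dfo had a median 0.16 ± 0.03 (SE over genes) above that of all genes (camera, p = 3.26e-06, and p = 0.0994 with an estimated correlation). Genes are not independent replicates, so this SE does not measure the spread between libraries. The 1695 genes lowered by Dfo had a median 0.0053 above that of all genes, with a camera p of 0.860, which leaves the explanation open. If the culture raised hypoxia-response genes, that list would rise in cultured XX too. Its mean lay -0.16 ± 0.11 (SE) from the mean of all genes, beside 2.28 for the same difference of means under Dfo. This argues against a rise above the level of E11.5 XX, for XX cells only. At E11.5 the list lay -0.25 from all genes in XY against XX (camera, adjusted p = 0.00604, and adjusted p = 0.535 with an estimated correlation). A higher level in E11.5 XX would hide part of a rise in culture.

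Sry could fall under Dfo because fewer of the cells were NR5A1(+), in which case its ratio to Nr5a1 would stay. The log2 ratio of Sry to Nr5a1 changed by -2.12 with Dfo (3 against 3 libraries with no overlap; exact permutation test, two-sided p = 0.1, the smallest that 3 against 3 can give). This value argues against a lower share of NR5A1(+) cells as the whole cause, while other causes, biological ones included, were not tested.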
